A study of Danio rerio with 5 samples.

How the data were processed

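Total RNA from zebrafish embryos at 72 h after fertilization was biotin-labelled and hybridised to Affymetrix zebrafish arrays, 1 sample per array. The labels place the 5 arrays in 3 groups: 2 arrays of control morphants, 2 of Bdh2 morphants and 1 of Bdh2 morphants that also received a synthetic mRNA for mouse Bdh2. Embryos had been injected at the 1- to 2-cell stage with morpholino at 130 µmol/L, and the added mRNA was at 50 µg/ml. The deposited values are probe set intensities on a linear scale, which the submitters' processing notes credit to Affymetrix Expression Console. The version, the summarisation algorithm and the scaling target are not given in the sources used here. The sorted values differed between arrays, so the table had not been quantile normalised. For arrays of this kind, the number of arrays limits the precision.

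Each intensity was converted to log2(intensity + 16), with no further normalisation. Of the 15617 probe sets, 115 Affymetrix control probe sets were set aside. The remaining probe sets were tested where their mean over the 5 arrays lay above the 40th percentile, which corresponds to an intensity of 97.6, and 9301 passed. The other 6201 were not tested. Gene symbols came from the array's own annotation: 10802 probe sets carried 1 symbol, 135 carried several and 4680 carried none. Their gene identifiers matched the reference gene table for 10718 probe sets, and 1 symbol was updated from it. The 9301 tested probe sets covered 6327 genes.

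All 5 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 and moderated with an intensity-dependent prior. The model leaves 2 residual degrees of freedom, all from the replicated groups, and the prior adds 4.89. The group with 1 array is assumed to vary like the other groups. Two-sided p-values were adjusted by Benjamini and Hochberg's method over the tested probe sets, with a threshold of 0.05. Differences are log2 differences with their standard error. The labels do not say whether replicates came from separate clutches, so a p-value here measures only the spread between these samples.

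Gene lists were tested with limma's camera function on 1 probe set per gene, the one with the highest mean, with a preset correlation between genes of 0.01. Of 38 lists, 37 had at least the 4 tested genes required, and their p-values were adjusted over the lists of a comparison. The lists, the threshold, the filter and most alternatives were chosen before the data were examined. The list test of the array with ectopic Bdh2 against controls was added afterwards. The same lists were also tested with an estimated correlation between genes and with limma's fry function. Differences of members were adjusted a second time over the list alone. List medians were set beside those of 10000 random lists matched on mean level, a comparison across genes, which are not independent replicates.

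The rule for named genes had 3 parts. The first was bdh2. The second took, in each comparison, the 10 highest and 10 lowest log2 differences among genes past the threshold whose replicates did not overlap between groups. Places left open were filled by the smallest unadjusted p. The third took up to 4 members, by the smallest p, of each list past the threshold and of the lists for globins, heme synthesis, erythroid cells, iron transport, autophagy and oxidative phosphorylation. Genes named outside the rule are said to be so.

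Recovery in the array with ectopic Bdh2 was described in arrays other than those used to choose the probe sets. The 200 probe sets with the largest difference between 1 Bdh2 morphant and 1 control array were taken. The remaining arrays measured how far the array with ectopic Bdh2 lay from the morphant, as a percent of the distance between morphant and control. Each distance is a median of differences signed by their direction in the pair that chose the probe sets. A positive median thus means that direction, not a higher value in the morphant. Both distances start from the same morphant array, so their ratio is not a test of recovery.

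Alternatives covered the moderation, the filter, the scaling between arrays, the added constant, the threshold, the choice of probe sets, a term for the replicate number and each array left out in turn. The labels do not say that the replicate number marks a batch, but control probe sets split by it. Results are therefore also given within each number and with the number as a block, in which the array with ectopic Bdh2 sits with replicate 1, the number in its label. Because spike-in controls of that array lie nearer replicate 2, the block was also run with it in block 2, an alternative added after the results were seen. The pipeline was tested on simulated data with the spread of these arrays, in 20 runs with 200 changed probe sets. In the comparison of Bdh2 morphants with controls, 13.8% of 2-fold and 86.8% of 4-fold changes were recovered. Against the single array with ectopic Bdh2, these shares were 7.7% and 60.8%. False calls made up 4.87% and 3.68% of calls. A simulated list of 35 genes shifted by -0.80 was recovered in 20 of 20 runs. The simulated noise was independent between genes and held no difference between replicate numbers. These runs therefore do not show how the calls of probe sets or lists hold where genes vary together.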

Results

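Transcript levels were measured in RNA of zebrafish embryos at 72 h after fertilization, in 2 control morphant arrays, 2 Bdh2 morphant arrays and 1 array of Bdh2 morphants that also expressed ectopic Bdh2. Bdh2 is a dehydrogenase of the short-chain family that has been linked to the mammalian siderophore, a small molecule that binds iron. The comparisons ask which transcripts differ when Bdh2 is targeted, and where they lie when Bdh2 is supplied again. Median intensity was 161 and 162 in control replicates 1 and 2, 157 and 142 in Bdh2 morphant replicates 1 and 2, and 174 with ectopic Bdh2.

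The arrays also split by replicate number. An Affymetrix control probe set read 129 and 139 in the replicate 1 arrays of the control and Bdh2 morphant groups, and 25644 and 34877 in their replicate 2 arrays. It read 184 with ectopic Bdh2, near replicate 1. In the same group order, the dap spike-in control read 1173 and 741 in replicate 1 and 167 and 206 in replicate 2. It read 158 with ectopic Bdh2, near replicate 2. The cre spike-in read 26316 and 25337, then 19115 and 22228, and 16426 with ectopic Bdh2, so these probe sets do not place that array with either number. Across probe sets it correlated at r = 0.911 and 0.909 with the replicate 1 arrays of controls and Bdh2 morphants, and at r = 0.876 and 0.835 with their replicate 2 arrays, nearer number 1. Across probe sets, which are not independent replicates, arrays with the same number were more alike (r = 0.964 and 0.952) than arrays of the same group (r = 0.932 for controls and 0.914 for Bdh2 morphants). Differences between replicates 2 and 1 in controls and in Bdh2 morphants correlated across probe sets at r = 0.538, whereas the morphant-control differences within the 2 numbers correlated at r = 0.156. For this reason the list medians of Bdh2 morphants against controls are followed by their values within number 1 and number 2. Leaving out a single array unbalances the numbers, so values without 1 array mix differences of group and of number.

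The bdh2 probe set passed the filter on mean intensity, which is not a call of presence in each array. Its intensity was 344 and 335 in the controls, 235 and 643 in the Bdh2 morphants and 142 with ectopic Bdh2. The morphant-control difference was 0.19 on the log2 scale (SE 0.50, n = 2 and 2; limma adjusted p = 1.00), which is less than the spread between the morphant arrays. It was -0.50 without Bdh2 morphant replicate 2 and 0.89 without replicate 1. The difference of the array with ectopic Bdh2 was -1.36 from Bdh2 morphants (SE 0.61; adjusted p = 0.428) and -1.17 from controls (SE 0.61; adjusted p = 0.736). The labels do not say whether the morpholino blocks splicing or translation, and the added mRNA is of mouse origin, so a zebrafish probe set need not record either.

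Against controls, the Bdh2 morphants had lower values of genes of the eye and of neurons. The lowest were crx, a homeobox gene of photoreceptor and bipolar cell development, and vsx1, a homeobox gene of retinal bipolar cells. The crx intensity was 1081 and 487 in controls and 42.6 and 14.1 in Bdh2 morphants, a log2 difference of -4.14 (SE 0.51). For vsx1 the intensities were 1197 and 644 against 110 and 65.7, a difference of -3.14 (SE 0.43). The crx values of both morphants and the lower vsx1 value lie under the filter intensity of 97.6, so the sizes depend on the constant added before the logarithm: with 64 in place of 16 they were -3.12 for crx and -2.65 for vsx1, and with 1 they were -4.82 and -3.36. Within replicate numbers 1 and 2 the differences were -4.23 and -4.06 for crx, and -3.27 and -3.01 for vsx1. Among neuronal genes, neurod1, a transcription factor of neuronal differentiation, differed by -1.90 (SE 0.49), aplp1, which codes for a relative of the amyloid precursor protein, by -1.41 (SE 0.33), and neurod6b by -1.36 (SE 0.35). No probe set passed the threshold over all 9301 tested (limma, smallest adjusted p = 0.555), and 194 had an unadjusted p under 0.05 where 465 would be expected by chance, 179 of them lower in Bdh2 morphants. With the replicate number as a block, 3 probe sets fell, those of crx (adjusted p = 0.0135), vsx1 (adjusted p = 0.0311) and the clone-named gene si:ch211-255g12.6 (-3.14, adjusted p = 0.0430), which lies outside the rule for named genes. Without control replicate 1 or 2 the count was 4 or 5, and without either morphant replicate it was 0.

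**Figure D1:**
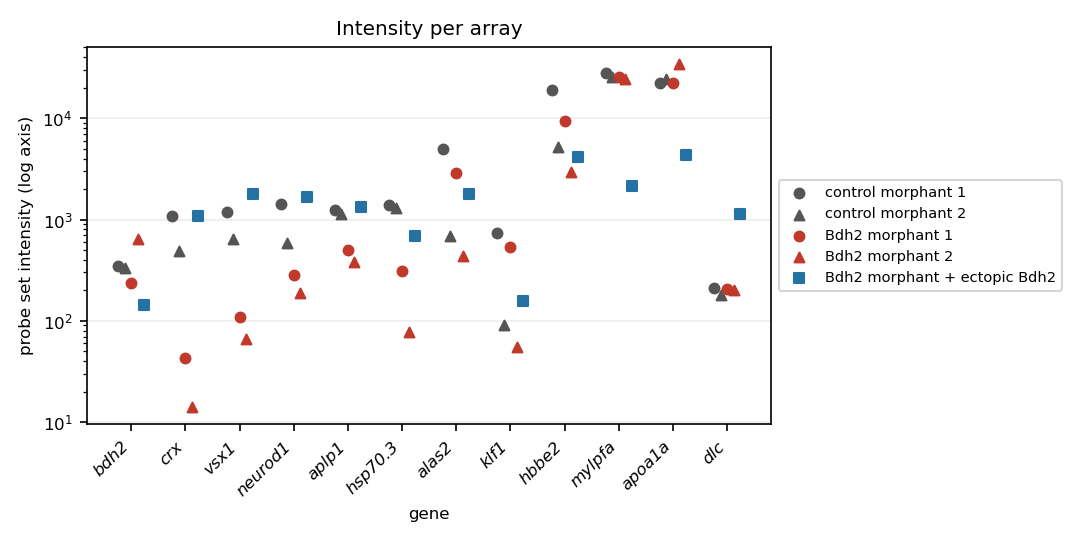
Intensity of 12 genes in each of the 5 arrays (vertical axis, log scale), with a point per array coloured by group and shaped by replicate number. For crx and vsx1 both Bdh2 morphant arrays lie at or below 110, and the lowest of the other arrays reads 487 for crx and 644 for vsx1.

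Other low values among single genes were those of hsp70.3, an inducible heat shock protein (-2.97, SE 0.58), col10a1a, a collagen of bone-forming cells (-2.54, SE 0.50), eef1a1a (-2.27, SE 0.51), ndrg1b (-2.08, SE 0.39), rlbp1a, a retinal-binding protein of the eye (-1.78, SE 0.42), slc13a2 (-1.59, SE 0.35) and slc25a4, a mitochondrial ADP/ATP carrier (-1.20, SE 0.29). The highest values were those of olig3, a transcription factor of the dorsal spinal cord and hindbrain (1.15, SE 0.35), acot14 (1.11, SE 0.33), the helicase genes ddx28 (1.05) and ddx21 (0.81), ccne1, which codes for cyclin E (0.95), mettl6 (0.93), egr2a (0.89), oip5 (0.86), rangap1b (0.83) and mapre1a (0.71). None of these passed the threshold over all genes, with or without the block.

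Gene lists gave a wider view of the same comparison. Of the 35 tested genes of neurons and synapse, 34 had lower values in Bdh2 morphants, with a median of -0.81 (within numbers -0.42 and -1.04; camera adjusted p = 1.28e-22, and adjusted p = 0.728 with an estimated correlation). The median was -0.39 without Bdh2 morphant replicate 2. The list of neural progenitors and glia did not differ (32 genes, median 0.02, within numbers -0.06 and -0.08; adjusted p = 0.319). Of 12 retina genes, 9 were lower, with a median of -0.32 (within numbers -0.13 and -0.63; adjusted p = 9.17e-05, and adjusted p = 0.728 with an estimated correlation). They included ckmt2a (-1.15) and rpe65a, an enzyme that regenerates the visual chromophore (-1.14), and the median was -0.52 without Bdh2 morphant replicate 1. All 7 lens genes had lower values, with a median of -0.93 (within numbers -1.11 and -0.83; adjusted p = 2.37e-04, and adjusted p = 0.728 with an estimated correlation), such as the crystallin genes crygm2c (-1.56), cryaa (-1.32) and crygmxl2 (-0.85). That lens median was 0.03 without control replicate 1 and -0.34 without Bdh2 morphant replicate 2, neither past the threshold. It was -1.87 without Bdh2 morphant replicate 1, -1.91 without control replicate 2 and -0.54 without the filter. In these lists 2 retina genes, 1 lens gene and 0 neuron genes passed when adjusted over the list alone.

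Muscle and skeletal genes were lower as groups too. In Bdh2 morphants 37 of 41 skeletal muscle genes were lower, with a median of -0.43 (within numbers -0.26 and -0.41; adjusted p = 2.15e-14, and adjusted p = 0.728 with an estimated correlation). Examples were ldb3a, which anchors the Z-disc (-1.17), the fast myosin gene myhz1.3 (-1.06), ldb3b (-0.87) and the tropomyosin gene tpma (-0.59). Of 21 cartilage and bone genes, 18 were lower, with a median of -0.50 (within numbers -0.35 and -0.48; adjusted p = 1.3e-06, and adjusted p = 0.728 with an estimated correlation), among them col5a2a (-0.82) and hapln1a (-0.71). The cartilage median was -0.19 without Bdh2 morphant replicate 2 and -0.27 without control replicate 1, and -0.29 without the filter. A ratio that is higher in degraded RNA was also higher in Bdh2 morphants within each number: the 3'/5' ratio of the muscle actin control acta1 was 4.28 in control and 11.8 in Bdh2 morphant replicate 1, 2.60 and 3.49 in replicate 2, and 6.63 with ectopic Bdh2. For gapdh it was 2.68 and 2.82 in replicate 1, 1.71 or lower in replicate 2, and 1.99 with ectopic Bdh2. When adjusted over the list alone, 1 cartilage and bone gene (col10a1a) and 0 muscle genes passed.

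Ribosomal protein genes moved the other way: 70 of 72 had higher values in Bdh2 morphants, with a median of 0.18 (within numbers 0.03 and 0.32; adjusted p = 2.68e-12, and adjusted p = 0.728 with an estimated correlation), for example rps4x (0.32) and rpl19 (0.30). After quantile normalisation the median was 0.03 and the list no longer passed (adjusted p = 0.128). It was 0.28 with each array centred, 0.10 without Bdh2 morphant replicate 2 and 0.07 without control replicate 2. Of 77 genes of the cell cycle and DNA replication, 56 were higher, with a median of 0.14 (within numbers 0.27 and 0.03; adjusted p = 0.00904, and adjusted p = 0.728 with an estimated correlation), among them orc2 (0.59), rfc4 (0.56) and h2ax (0.48). That call was lost without Bdh2 morphant replicate 1 (median 0.04) and without control replicate 1 (0.07). The median was 0.25 with each array centred and 0.23 without Bdh2 morphant replicate 2. Neither list had a gene past the threshold adjusted over the list alone.

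The calls of 4 further lists depended on which arrays were in the fit, and for each the adjusted p = 0.728 with an estimated correlation. Of 19 hypoxia response genes 17 were lower, with a median of -0.28 (within numbers -0.08 and -0.73; adjusted p = 1.39e-04), such as p4ha1b (-1.16), the lactate dehydrogenase gene ldha (-1.03) and eno1a (-0.63). Of 26 genes of the endoplasmic reticulum stress and amino acid response 20 were lower, with a median of -0.23 (within numbers -0.31 and -0.22; adjusted p = 0.0019), such as aldh18a1, an enzyme of proline synthesis (-1.72), atf3 (-0.77), chac1 (-0.71) and calr (-0.69). Of 12 genes of the endocrine pancreas and gut hormones 10 were lower, with a median of -0.39 (within numbers -0.13 and -0.70; adjusted p = 0.00736); scg3 differed by -0.74 and scg5 by -0.67, while the somatostatin gene sst2 was at 0.68. Of 24 genes of extracellular matrix proteases and fibrosis 18 were lower, with a median of -0.24 (within numbers 0.02 and -0.49; adjusted p = 0.0209), such as mmp13a (-1.19), timp2a (-0.74) and col6a3 (-0.72). Without Bdh2 morphant replicate 2 the medians were -0.20, -0.07, -0.08 and -0.10 in that order and no call was kept. Without control replicate 1 the median of the stress list was -0.01, and without control replicate 2 those of the hypoxia and matrix lists were -0.16 and -0.12, all 3 short of the threshold. Without Bdh2 morphant replicate 1 the medians were -0.72, -0.40, -0.77 and -0.37 in the same order. Without the filter the endocrine and matrix calls were lost (adjusted p = 0.0955 and 0.0629), and with each array centred the hypoxia, stress and matrix medians were -0.17, -0.13 and -0.14. With the replicate block all 4 passed (adjusted p = 1.77e-04, 7.49e-04, 0.00311 and 0.0292 in that order, and adjusted p = 0.728 with an estimated correlation and no block). The hypoxia gene ndrg1b passed adjusted over the list alone, and 0 genes of the other 3 lists did.

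Genes of heme and iron, the processes linked to the siderophore, did not differ past the threshold as lists when all arrays were used without a block. Of 10 tested genes of heme synthesis and mitochondrial iron supply 9 were lower, with a median of -0.29 (within numbers -0.32 and -0.35; adjusted p = 0.0745), and of 21 erythroid genes 19 were lower, with a median of -0.35 (within numbers -0.43 and -0.22; adjusted p = 0.0745). With the replicate number as a block both lists passed (adjusted p = 0.00789 and 3.64e-04, camera). With an estimated correlation and no block neither did (adjusted p = 0.728 for heme and 0.946 for erythroid genes). Examples were fech, which inserts iron into heme (-0.76), clpxa (-0.53), uros (-0.35) and tmem14ca (-0.29) for heme, and the carbonic anhydrase gene cahz (-0.69), lmo2 (-0.52) and tmod4 (-0.50) for erythroid cells. Several of these medians changed sign with 1 array left out, which sets unlike replicate numbers against each other. Between numbers, replicate 2 minus replicate 1, the erythroid median was -1.38 in controls and -1.39 in Bdh2 morphants. The erythroid values with an array left out therefore do not measure the morphant difference alone. Without Bdh2 morphant replicate 2 the heme median was 0.17 and the erythroid median 0.41, neither past the threshold, while without control replicate 1 the erythroid median was 0.38 and passed as higher (adjusted p = 6.56e-04). Without Bdh2 morphant replicate 1 the erythroid median was -1.01 and passed as lower (adjusted p = 4.66e-05), as did the heme median at -0.43 (adjusted p = 0.0360). Without control replicate 2 the erythroid, heme and globin medians were -0.93, -0.47 and -0.54, and each passed as lower (adjusted p = 5.46e-14, 0.00299 and 4.49e-04). Globins (median -0.31, within numbers 0.01 and -0.34; adjusted p = 0.658) included hbbe2 at -0.92, hbaa1 at -0.73 and hbae3 at 0.10, and the globin median ran from -0.95 without Bdh2 morphant replicate 1 (adjusted p = 0.0345) to 0.34 without replicate 2 (adjusted p = 0.216; with all arrays and an estimated correlation adjusted p = 0.946). The iron transport and storage list (median 0.03, within numbers 0.04 and 0.03; adjusted p = 0.87) included the iron exporter slc40a1 at 0.40 and the ferritin receptor ncoa4 at -0.34. Autophagy and mitophagy genes (median -0.12, within numbers -0.23 and -0.07; adjusted p = 0.233) included lamp1b at -0.66 and calcoco1a at -0.65, and oxidative phosphorylation genes (median 0.02, within numbers -0.11 and 0.17; adjusted p = 0.805, and adjusted p = 0.946 with an estimated correlation) included ndufa4b at -1.09 and -0.91 within numbers and ndufa1 at -0.52. The oxidative phosphorylation median was -0.15 without Bdh2 morphant replicate 2 (adjusted p = 9.57e-04) and 0.21 without replicate 1 (adjusted p = 5.35e-04), past the threshold in opposite directions. In these lists 0 genes passed adjusted over the list alone.

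In all, 11 of 37 lists passed in this comparison with the preset correlation, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 0 with fry (smallest adjusted p = 0.934, 1 at an unadjusted p under 0.05).

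Against Bdh2 morphants, the array with ectopic Bdh2 had higher crx and vsx1 and much lower muscle and liver transcripts. The crx intensity was 1089 and that of vsx1 1778, log2 differences of 4.72 (SE 0.63; adjusted p = 0.0359) and 4.15 (SE 0.53; adjusted p = 0.0299) from Bdh2 morphants. With 64 as the added constant they were 3.66 and 3.62, since the morphant values are low, and without the filter neither passed (adjusted p = 0.108 for crx and 0.0901 for vsx1). These were the 2 genes that rose past the threshold, and 47 probe sets fell. The lowest were pvalb4, a calcium-binding parvalbumin of fast muscle (-4.50, SE 0.37), the myosin light chain genes myl13 (-4.45, SE 0.30), myl10 (-4.29, SE 0.34) and mylpfa (-3.53, SE 0.22), tmem38a, a cation channel of the sarcoplasmic reticulum (-3.55, SE 0.36), nme2b.2 (-3.45, SE 0.28), the slow myosin gene smyhc1 (-3.23, SE 0.40), tmx2a (-3.16, SE 0.46), the troponin gene tnni2a.4 (-3.10, SE 0.27) and ak1 (-3.05, SE 0.27). The mylpfa intensity was 25478 and 24193 in Bdh2 morphants, 27696 and 25700 in controls, and 2132 with ectopic Bdh2. Single genes with high values that did not pass without a block were foxg1b, a forebrain transcription factor (3.13, adjusted p = 0.130), otpb (2.89), ndrg1b (2.75), dlc, a Notch ligand (2.38, adjusted p = 0.0856), klf11a (2.25) and slc32a1, the vesicular transporter of GABA and glycine (2.25), with sik1 and pbx3b 6.50-fold and 5.64-fold higher. With the replicate block all of these but slc32a1 passed. The median over all tested probe sets was 0.12 higher with ectopic Bdh2 than in Bdh2 morphants, and 0.12 higher than in controls. The 49 calls rest on a single array with no replicate. Their number was 0 without Bdh2 morphant replicate 2, 58 without replicate 1, 216 and 222 without control replicates 1 and 2, and 151 with the replicate block. With that array moved to block 2 it was 823, so the blocked counts rest on its placement. Without the intensity trend in the moderation the count was 0, and without the filter it was 17.

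Skeletal muscle, liver and intestine gave the lowest list medians in this comparison. The heart and exocrine pancreas lists were at 0.06 and 0.16 and did not pass (camera adjusted p = 0.911 and 0.629). Of 41 skeletal muscle genes 39 were lower and 22 fell past the threshold over all genes, and 33 did so adjusted over the list alone. The muscle median was -2.44 (-2.48 and -2.40 from Bdh2 morphant replicates 1 and 2; camera adjusted p = 8.64e-44, and adjusted p = 0.309 with an estimated correlation). All 26 genes of the liver and plasma proteins were lower, 5 past the threshold over all genes and 26 adjusted over the list alone, with a median of -2.48 (-2.00 and -3.02 by array; adjusted p = 1.9e-28, and adjusted p = 0.522 with an estimated correlation). The apolipoprotein genes apoa1a (-2.65), apoc1 (-2.59), apobb.1 (-2.15) and apoa2 (-2.07) fell. Of 11 intestine genes 8 were lower, with a median of -2.26 (-1.76 and -2.16 by array; adjusted p = 1.05e-04, and adjusted p = 0.522 with an estimated correlation), such as the fatty acid-binding genes fabp2 (-3.58) and fabp1b.1 (-3.39) and the apolipoprotein genes apoa4b.2 (-3.56) and apoa4b.1 (-2.92). Without the filter on low values the intestine median was -0.18 (adjusted p = 0.0188). Adjusted over the list alone, 7 intestine genes were lower and 1 higher. Of 21 cartilage and bone genes 15 were lower, with a median of -0.71 (-0.92 and -0.77 by array; adjusted p = 7.62e-05, and adjusted p = 0.522 with an estimated correlation). The cartilage collagen gene col9a3 fell (-3.03, adjusted p = 0.0299). Without a block col2a1a (-2.90), col9a1b (-2.83) and col9a2 (-2.67) did not pass, and with the replicate block they did. Adjusted over the list alone, 6 genes passed. The cartilage median was -0.31 without the filter.

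**Figure D2:**
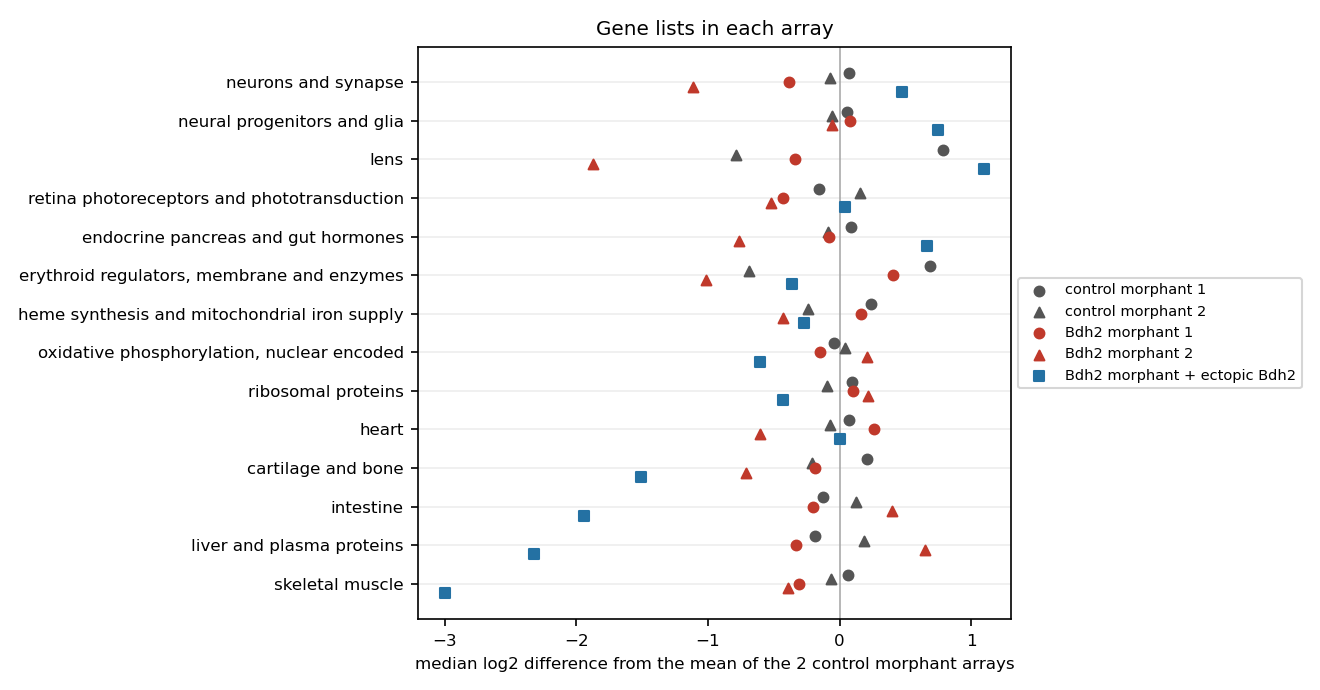
Median log2 difference of 14 gene lists from the mean of the 2 control arrays (horizontal axis), with a point per array. The array with ectopic Bdh2 lies at -2.99 for skeletal muscle and -2.32 for liver and plasma proteins, far from the 4 other arrays. Within the list of neurons and synapse, the Bdh2 morphant arrays lie below the control arrays and the array with ectopic Bdh2.

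Neural, lens and hormone genes lay higher with ectopic Bdh2 than in Bdh2 morphants. In this single array 18 of 19 forebrain and midbrain genes were also highest, with a median 1.08 above the control mean. A difference in the tissue sampled was not tested for these lists, nor for crx and vsx1. Their higher values can therefore not be read as recovery. Of 35 genes of neurons and synapse 31 were higher, with a median of 1.15 (0.79 and 1.55 from Bdh2 morphant replicates 1 and 2; adjusted p = 9.22e-10, and adjusted p = 0.587 with an estimated correlation), among them neurod1 (2.75), neurod4 (2.03) and aplp1 (1.57). Of 32 genes of neural progenitors and glia 24 were higher, with a median of 0.73 (adjusted p = 3.84e-04, and adjusted p = 0.522 with an estimated correlation), such as olig2, a transcription factor of the oligodendrocyte lineage (2.18), and the proneural gene ascl1a (1.70), while the glial glutamate transporter gene slc1a3a was at -1.76. All 7 lens genes were higher, with a median of 1.65 (adjusted p = 6.99e-04, and adjusted p = 0.588 with an estimated correlation), cryaa by 3.11, and the median was 1.08 with the replicate block and 0.90 without the filter. The retina list did not pass (12 genes, median 0.29, adjusted p = 0.106). All 12 genes of the endocrine pancreas and gut hormones were higher, with a median of 1.02 (adjusted p = 1.22e-04, and adjusted p = 0.522 with an estimated correlation), such as ins (1.90), which codes for insulin, and gcga (3.04-fold higher), which codes for glucagon. Without Bdh2 morphant replicate 2 that median was 0.68. Adjusted over the list alone, 13 neuron genes, 3 endocrine genes, 0 lens genes, and 7 progenitor and glia genes were higher, with 2 progenitor and glia genes lower.

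Lists of housekeeping processes had lower values with ectopic Bdh2 than in Bdh2 morphants. Of 72 ribosomal protein genes 71 were lower, with a median of -0.59 (adjusted p = 1.9e-28, and adjusted p = 0.522 with an estimated correlation), rpl19 by -0.78, but after quantile normalisation the median was -0.05 (adjusted p = 0.634). Of 73 oxidative phosphorylation genes 71 were lower, with a median of -0.61 (adjusted p = 1.01e-15, and adjusted p = 0.522 with an estimated correlation), such as uqcrh (-1.20) and atp5mc3b (-1.18), and the median was -0.40 after quantile normalisation. The citric acid cycle list (24 genes, median -0.45, adjusted p = 0.0114), with mdh1ab at -2.13, and the oxidative stress list (21 genes, median -0.42, adjusted p = 0.0162), with the glutathione peroxidase gene gpx4a at -2.86, were also lower. Both lost their call after quantile normalisation (adjusted p = 0.0646 and 0.061), and each had an adjusted p = 0.522 with an estimated correlation. The iron-sulfur cluster list had 11 of 12 genes lower, with a median of -0.46 (adjusted p = 0.0183, and adjusted p = 0.522 with an estimated correlation) and glrx5 at -0.80. Its call was lost without Bdh2 morphant replicate 2 (median -0.31) and without control replicate 1 or 2. There were 2 citric acid cycle genes past the threshold adjusted over the list alone, and 0 genes of the other 4 lists.

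A last set of lists passed by less. The epidermis list (34 genes, median -0.52, adjusted p = 0.00723), with krt5 at -1.19 and krt8 at -1.08, had an adjusted p = 0.588 with an estimated correlation, and a median of -0.17 after quantile normalisation, where it no longer passed. The pigment cell list (12 genes, median -0.47, adjusted p = 0.0183) had its lowest values in paics (-1.51) and gart (-1.35), which code for enzymes of purine synthesis, and an adjusted p = 0.522 with an estimated correlation. Its median was -0.27 without Bdh2 morphant replicate 2, where it no longer passed, -0.72 without replicate 1 and -0.21 without the filter. The list of blood stem and lymphoid cells (8 genes, median 0.96, adjusted p = 0.0183, and adjusted p = 0.522 with an estimated correlation) was higher through lef1 (1.76), meis1b (1.07), tox (0.98) and gata3 (0.95), transcription factor genes with expression outside blood as well. It did not pass without Bdh2 morphant replicate 2 (median 0.73), after quantile normalisation (0.78) or without the filter (0.37, adjusted p = 0.323). The matrix list (24 genes, median -0.17, adjusted p = 0.0445, and adjusted p = 0.633 with an estimated correlation) held the protease genes ctsba (-1.98) and ctsla (-1.53) and mmp11b at 2.21. Its median was 0.02 without Bdh2 morphant replicate 1 and -0.43 without replicate 2, and its call was also lost without either control and with each array centred (median -0.37, adjusted p = 0.0537). A single pigment cell gene passed adjusted over the list alone, and 0 genes of the other 3 lists did.

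Heme, erythroid and globin lists did not differ past the threshold between the array with ectopic Bdh2 and Bdh2 morphants when all arrays were used without a block. The erythroid median was 0.04 (camera adjusted p = 0.612), and -0.64 with the replicate block, a value that passed (adjusted p = 4.9e-06). That block moves the morphant level to replicate 1 by the difference between numbers, estimated from controls and Bdh2 morphants together. Without Bdh2 morphant replicate 2 the erythroid median was -0.61. With the array in block 2 the erythroid median was 0.72 and passed as higher (adjusted p = 0.0112), so no direction can be read. With an estimated correlation and no block the adjusted p = 0.957. Single genes included tmod4 at -2.14, a tropomodulin of muscle as well as of blood cells, and klf17 at -1.24. The heme median was 0.19 (adjusted p = 0.995), with urod at -1.08 and clpxa at 0.80, and the globin median was -0.38 (adjusted p = 0.248), with hbbe3 at -0.66. Without Bdh2 morphant replicate 2 the globin median was -1.03 and passed (adjusted p = 0.00711), as did iron transport and storage at -0.50 (adjusted p = 0.0118). With the replicate block both also passed as lower, globins at -0.83 (adjusted p = 0.00504) and iron transport and storage at -0.51 (adjusted p = 0.0195). With the array in block 2 neither passed (medians 0.19 and 0.04, adjusted p = 0.998 and 0.644), so these calls depend on its placement. With an estimated correlation and all arrays these 2 lists had adjusted p = 0.720 and 0.633. Iron transport and storage (median -0.28, adjusted p = 0.134) included tfa, which codes for transferrin, at -2.82 and cp at -1.28, both made by the liver. Autophagy and mitophagy (median 0.15, adjusted p = 0.326) included ulk1b at 1.72 and calcoco1a at 1.16. Of all 37 lists, 17 passed with the preset correlation, 0 with an estimated correlation (1 at an unadjusted p under 0.05), 0 with fry (smallest adjusted p = 0.105, 4 at an unadjusted p under 0.05) and 20 with the replicate block (18 with the array in block 2).

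Against controls, the array with ectopic Bdh2 was lowest in muscle genes, while crx and vsx1 lay near or above the control arrays. Of 9301 probe sets 62 fell and 0 rose past the threshold (limma), with 219 higher and 434 lower at an unadjusted p under 0.05. With the replicate block 9 rose and 126 fell, and with the array in block 2 it was 127 and 266. Without the intensity trend in the moderation 40 passed, and without the filter 38. The lowest genes were pvalb4 (-5.06, SE 0.37), myl13 (-4.46), myl10 (-4.30), smyhc1 (-3.92), srl, which codes for sarcalumenin (-3.81), nme2b.2 (-3.80), lims2 (-3.80), the Z-disc gene myoz1b (-3.76), slc25a4 (-3.73) and tmem38a (-3.69), all past the threshold. The highest values, none past it, were those of dlc (2.43, adjusted p = 0.0724), dbx1a, a transcription factor of spinal interneurons (2.05), fam222aa (1.88), olig3 (1.83), dusp1 (1.83), gcga (1.77), trappc2 (1.76), ascl1a (1.72), clk4a (1.58) and lrrn1 (1.47). The count was 132 without control replicate 1, 109 without control replicate 2 and 84 without either Bdh2 morphant array.

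The list test of this comparison was not planned and was added after the data were seen. All 41 skeletal muscle genes were lower with ectopic Bdh2 than in controls, 26 past the threshold over all genes and 34 adjusted over the list alone, with a median of -2.99 (adjusted p = 5.05e-66, and adjusted p = 0.203 with an estimated correlation). It was also the list that passed with fry (adjusted p = 0.0383). All 26 liver genes were lower (median -2.32), as were 9 of 11 intestine genes (median -1.94) and 17 of 21 cartilage and bone genes (median -1.51), each with an adjusted p = 0.475 with an estimated correlation. Without the filter the intestine and cartilage medians were -0.26 and -0.67. Adjusted over the list alone, 25 liver, 7 intestine and 12 cartilage and bone genes passed. The lists of oxidative phosphorylation (-0.61), matrix proteases (-0.55), the citric acid cycle (-0.51), pigment cells (-0.46), oxidative stress (-0.41) and lysosome (-0.20) were lower, and those of neural progenitors (0.74) and the cell cycle (0.35) higher, all with adjusted p = 0.475 with an estimated correlation. Of these, the oxidative stress, pigment and cell cycle calls were lost without control replicate 1 and the lysosome call without control replicate 2, and the matrix median was -0.83 without control replicate 1. The endocrine list was higher (0.66, adjusted p = 0.0106, and adjusted p = 0.635 with an estimated correlation), with a median of 0.31 without control replicate 2 and 0.13 with the replicate block. Epidermis (-0.26, adjusted p = 0.0156, and adjusted p = 0.638 with an estimated correlation) was at 0.01 after quantile normalisation and at -0.10 without control replicate 1, both short of the threshold, and at -0.57 without control replicate 2. Ribosomal protein genes (-0.43, adjusted p = 1.11e-20, and adjusted p = 0.475 with an estimated correlation) were at -0.01 after quantile normalisation (adjusted p = 0.89). Adjusted over the list alone, 1 gene of each of the citric acid, neural progenitor and endocrine lists passed and 0 of the other lists of this group. The neuron list, which was low in Bdh2 morphants, had a median of 0.47 above controls and did not pass (adjusted p = 0.0831, and adjusted p = 0.772 with an estimated correlation). Its median was 0.09 with the replicate block (adjusted p = 0.375), 0.57 with the array in block 2 (adjusted p = 0.00783) and 0.23 without control replicate 2 (adjusted p = 0.129). It passed without Bdh2 morphant replicate 1 or 2 (adjusted p = 0.0446 and 0.0435), which leaves the median as it was. In all, 15 lists passed with the preset correlation, 0 with an estimated one (1 at an unadjusted p under 0.05), 1 with fry (5 at an unadjusted p under 0.05) and 22 with the replicate block (17 with the array in block 2).

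The array with ectopic Bdh2 also differed from controls in genes of position along the body axis, which were chosen after their values were seen. Of the hox genes, which pattern the body from head to tail, the 10 tested members of paralog groups 9 to 13 had a median of -1.83 (SE of the median over genes 0.25), with 9 lower than in each of the 4 other arrays. Examples were hoxb9a (-2.79), hoxb10a (-2.26) and hoxd10a (-2.07). The 9 genes of groups 5 to 8 had a median of -1.30 (SE 0.20) and the 9 of groups 1 to 4 a median of -0.03 (SE 0.14). Of 19 tested genes of forebrain and midbrain regions 18 were highest in this array, with a median of 1.08 (SE 0.09), among them barhl2 (1.68), lhx9 (1.61) and otx2b (1.55). The medians of the posterior hox and brain genes were -1.92 and 1.00 after quantile normalisation. Between Bdh2 morphants and controls, the posterior hox median within numbers 1 and 2 was -0.82 and -0.02, and that of the brain genes was -0.45 in each. Control replicate 2 differed from control replicate 1 by a median of -0.40 for the brain genes and 0.12 for the posterior hox genes. The intensity of tbxta, a gene of the notochord and tail bud, was 33.4 with ectopic Bdh2, 294 and 155 in controls, and 262 and 234 in Bdh2 morphants.

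**Figure D3:**
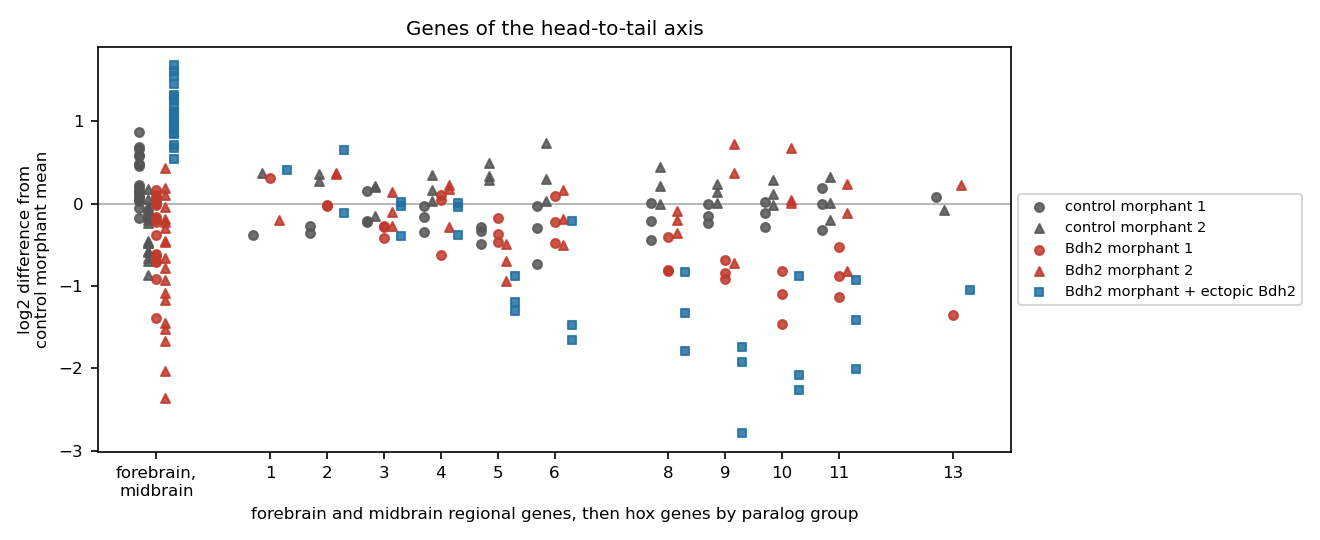
Log2 difference from the control mean (vertical axis) of forebrain and midbrain genes and of hox genes by paralog group (horizontal axis), with a point per gene for each of the 5 arrays. In the array with ectopic Bdh2 the brain genes have a median of 1.08, groups 1 to 4 of -0.03 and groups 9 to 13 of -1.83.

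Recovery with ectopic Bdh2 cannot be read from these arrays. For the 200 probe sets that differed most between replicate 1 of Bdh2 morphants and controls, differences elsewhere were signed by their direction in replicate 1. The median signed difference of Bdh2 morphant replicate 2 was 0.41 from control replicate 2 and 0.60 from the array with ectopic Bdh2, a ratio of 144%. For those chosen and signed in replicate 2, the values in replicate 1 were 0.32 and 0.67, a ratio of 206%. Both medians of a ratio come from the same morphant array, and with 2 such arrays no value for the absence of recovery can be measured. Where the chosen arrays had unlike numbers, the morphant-control medians were -1.22 and -0.47. In such pairs the difference between numbers enters the choosing and the measuring arrays with opposite signs. The split alone can therefore give negative medians. Across all tested probe sets, morphant-control differences correlated with the differences of the other morphant array from the array with ectopic Bdh2 at r = 0.09 and 0.22 for pairs of the same number, and at r = -0.32 and 0.16 for pairs of unlike numbers.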

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

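The placement of the array with ectopic Bdh2 in block 2, the list test of the array with ectopic Bdh2 against controls with its alternatives, and the list test on the 4 control and Bdh2 morphant arrays alone, were chosen after seeing the data, as was the restriction of the list medians below to the lists reported in the text. With 1 or 2 arrays per group, and intensities under 97.6 left untested, changes of 2-fold would mostly be missed. Settings of the moderation, the filter, the threshold and the choice of probe sets leave a gene's log2 difference as it is. Under those settings a gene's direction could not reverse, so the counts for genes overstate how much was put to the test. Of the named genes' values under other settings, 2707 kept direction and side of the threshold, 102 gained a call, 30 lost one and 4 reversed. For list medians these counts were 264, 8, 99 and 14. With an array left out they were 718, 68, 23 and 11 for genes and 172, 11, 22 and 15 for lists, where the omission also unbalances the replicate numbers. Except for the blocks, which move the other groups to the number set for the array with ectopic Bdh2, the cause was not tested. With an estimated correlation, 0 lists passed in each comparison, and with fry 0, 0 and 1 (morphant against control, ectopic against morphant, ectopic against control). In that order, the replicate block gave 3, 151 and 135 probe sets, and the last 2 were 823 and 393 in block 2. Ectopic against morphant, there were 0 without the intensity trend, 17 without the filter and 77 at an adjusted p under 0.1. Ectopic against control, there were 40 without the trend and 38 without the filter. The ratios not read as recovery were 197% and 253% with 100 probe sets.

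Reversals outside left-out arrays were these. Ectopic against morphant, the erythroid median was -0.64 with the block, -0.16 with arrays centred, -0.15 without the filter and -0.087 after quantile normalisation, heme was -0.42 with the block and -0.017 with arrays centred, and autophagy was -0.052 with arrays centred. In block 2 globins were at 0.19, iron transport at 0.042 and hbbe2 at 0.55. After quantile normalisation iron transport was 0.073, fthl27 0.17 and hbae3 0.17. Morphant against control, globins were 0.10 and iron transport -0.031 without the filter, and oxidative phosphorylation was -0.0030 and hbae3 -0.075 after quantile normalisation. Ectopic against control, epidermis was 0.0072 after quantile normalisation.

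With arrays left out in turn, probe set counts ran from 0 to 5 (morphant against control), 0 to 222 (ectopic against morphant) and 84 to 132 (ectopic against control). Morphant against control, log2 ranges were -0.50 to 0.89 for bdh2, -1.01 to 0.41 for erythroid genes, -0.95 to 0.34 for globins, -0.47 to 0.17 for heme, -0.15 to 0.22 for iron transport, -0.15 to 0.21 for oxidative phosphorylation, -1.91 to 0.032 for lens, -1.78 to 0.40 for cahz, -1.79 to 0.28 for fech, -2.01 to 0.55 for hbaa1, -0.19 to 0.39 for hbae3, -1.86 to 0.0099 for hbbe2 and -0.90 to 0.22 for ncoa4. Ectopic against morphant, they were -0.61 to 0.68 for erythroid genes, -1.03 to 0.16 for globins, -0.51 to 0.45 for heme, -0.50 to 0.0044 for iron transport, -0.43 to 0.018 for matrix genes and -1.16 to 0.50 for hbbe2.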

Other observations

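The tests on hox and islet hormone genes, on p53 targets, on the split between replicate numbers, on random lists matched in level and on the most abundant globins were chosen after the result was seen, and muscle was weighed apart from liver and intestine once those values were known. Red blood cell genes differed between the replicate numbers more than between the groups. The erythroid median of replicate 2 minus replicate 1 was -1.38 in controls and -1.39 in Bdh2 morphants. The heme enzyme gene alas2 was at -2.82 and -2.65, the erythroid transcription factor genes klf1 at -2.80 and -2.95 and gata1a at -2.14 and -2.01, and the membrane genes epb41b at -2.96 and -2.70 and slc4a1a at -2.20 and -1.89. Myeloid genes were at -0.76 and -1.05. Single genes in this paragraph were chosen after their values were seen.

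The first pattern is this lower erythroid list in both replicate 2 arrays. A shift of all genes of like level is argued against: the median closer to 0 was -1.38, below all 10000 random lists matched on mean level. A lower share of red blood cells in the replicate 2 samples remains open, since the globin genes hbae3 and hbbe3 differed by -0.53 but lie above 99.7% of probe sets, near the top of the scale, where a change may be compressed. The labels name no biological difference between the numbers, and none was tested. However, 1 control probe set read 129 and 139 in the replicate 1 arrays of controls and Bdh2 morphants. In their replicate 2 arrays it read 25644 and 34877. What it measures was not established here, so a biological difference between the samples stays possible.

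The second pattern is the low skeletal muscle, liver, intestine and cartilage lists with ectopic Bdh2. Scaling of that array is argued against, because the muscle median was -2.93 from the control mean after quantile normalisation. For muscle, a smaller share of trunk and tail tissue in the sample could account for part of the pattern: the posterior hox genes were at -1.83 (SE 0.25) and the anterior ones at -0.03 (SE 0.14), although in Bdh2 morphant replicate 1 the posterior ones were at -0.82 from its control with muscle at -0.26. For liver and intestine, 4 islet hormone genes, also of the trunk, lay 1.62 above the control mean (SE over genes 0.32). These genes were chosen after the result was seen, in a single array, so they cannot decide on that share. An earlier stage of these embryos stays open, as the early-stage list was at -0.26 (SE 0.57, 7 tested genes of 25 on the array). That is the side set beforehand against an earlier stage, but within its standard error. The tested genes include tbxta of the tail bud (-2.22) and myod1 of the muscle list (-0.94). They also include otx1 of the brain genes (1.32), and the others lay from -0.59 to 0.88. The median therefore cannot tell stage from the muscle and axis differences of this array. An effect of the ectopic Bdh2 itself cannot be separated from those of a single unreplicated sample.

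The third pattern is the low neuron list in Bdh2 morphants. The median was below 0 within both numbers (-0.42 and -1.04), which argues against the split between replicate numbers as the cause. Both values lay below all 10000 matched random lists. Between the morphant arrays, replicate 2 minus replicate 1, the median was -0.60, at percentile 0.02 of such lists. The random lists therefore cannot exclude variation between single arrays. Activation of p53 by the morpholino cannot be told apart, because 2 of its 4 target genes were on the array and their median was 0.88 within number 1 and -1.10 within number 2, while the wider p53 list of 17 genes was at 0.28 and -0.47 but also 0.43 higher in control replicate 2 than in control replicate 1. Delayed development stays open too. The early-stage list was at -0.19 (SE 0.23) and -0.33 (SE 0.24) within numbers 1 and 2, the side set beforehand against a delay. The value within number 1 is smaller than its standard error, and 7 of the 25 early-stage genes on the array were tested. Among these 7 are myod1 of the muscle list and otx1 of the brain genes, lists that were themselves low in Bdh2 morphants. Forebrain and midbrain genes were also at -0.45 within each number, while the neural progenitor list did not differ. The acta1 ratio that is higher in degraded RNA was 11.8 in Bdh2 morphant and 4.28 in control replicate 1, and 3.49 and 2.60 in replicate 2. Neither tissue share nor RNA quality was tested for the neuron list. Loss of Bdh2 function is the biological explanation that the design offers, and these tests cannot separate it from these or from other effects of this morpholino.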
